A study of Homo sapiens with 6 samples.

How the data were processed

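The samples were 6 RNA sequencing libraries of the uveal melanoma line 92.1, 3 treated with DMSO and 3 with 0.1 µM LBH589 for 24 h. Total RNA was extracted with Trizol and 1 µg was made into libraries with a TruSeq RNA kit, per the labels' protocols. The deposited files give 1 FPKM value per transcript and library, per the file headers. Bowtie 0.12.2 and the human build hg19 are named in the submitters' processing notes, without their roles, and the quantification tool, the annotation release and the filter on transcripts are not given in the sources used here. Each of the 30624 listed transcripts has a mean of at least 0.5 FPKM in one group or the other (lowest 0.500), so the listing follows the group means, and nearly all, 30430, are protein-coding transcripts. Per-sample FPKM does not depend on the other libraries, but a transcript under that level in both groups was not analysed here.

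Transcripts were named by their identifiers through the GENCODE release 29 transcripts. That release uses a later genome build than the files, so no coordinates were taken from it. Names were found for 30504 transcripts (99.6%), and FPKM was summed over the listed transcripts of each gene, which gave 12010 genes, 4484 of them with 1 listed transcript. The 120 unnamed transcripts held between 0.106 and 0.142% of FPKM per library. Summing removes the split of fragments between transcripts of a gene, but it adds values that were divided by different transcript lengths. No pair of libraries shared more than 1 exactly equal transcript value above 0.

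The planned count tests could not be used, because the files hold FPKM and not counts, and the plan's test for such values was used instead. Genes with a mean of at least 0.5 FPKM over the 6 libraries (11520) were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a trend on mean expression, robust moderation and treatment as the only term, and p-values were adjusted by Benjamini-Hochberg. A gene was called at adjusted p below 0.05. Fold changes are differences of mean log2(FPKM + 1), LBH589 minus DMSO. Sums and shares per library were compared with exact two-sided permutation tests (scipy 1.17.1), which cannot go below p = 0.1 for 3 against 3.

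For 43 gene lists, written before the data were examined, members were counted as risen or fallen. The 36 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, called at adjusted p below 0.05 over the lists, and again with an estimated correlation and with fry. The rule for named genes, also written beforehand, took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM (2113 and 1952 candidates). It added METTL14, METTL3, FAT4, ALKBH5, FTO, CDKN1A, BAP1, MITF and the HDAC genes whatever their values, and in each list up to 4 tested members with the smallest adjusted p. Members that did not pass are given by value, and some genes that the rule takes are not reported here. Gene families in the closing part were chosen after the values were seen.

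FPKM multiplied by transcript length piled up at a step and at 2 times that step in 4 libraries. These piles held 29, 23 and 45 values in DMSO replicates 1 to 3, against at most 11, 14 and 11 elsewhere. In LBH589 replicate 3 the pile held 17 values against at most 10. If a step means equal fragments in each library, DMSO replicates 2 and 3 had 1.12 and 0.82 times the depth of DMSO replicate 1. LBH589 replicate 3 then had 0.99 times that depth. No step was found in LBH589 replicates 1 and 2 within the range searched. How many fragments 1 step stands for was not checked, so absolute depth was not estimated and no counting interval can be given. An exact 0 in these files may be a failed estimate for a transcript: housekeeping genes had single transcripts at 0, but no housekeeping gene checked was at 0 in its sum. A gene at 0 in a library is therefore described as listed at 0.

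The test was checked on simulated data with the means and residual spread of the 11520 genes, in which 200 genes with a mean log2 value of at least 3 were changed. It recovered 9.0% of changes of 0.5, 53.7% of changes of 1 and 86.4% of changes of 2 on the log2 scale, with 3 false calls. In a simulation of 36 lists of 40 genes, camera called the 1 shifted list and 0 of the others. Simulated genes were drawn independently, so this cannot check the preset correlation. Only 200 genes or 1 list were changed, while 48.8% of the real genes were called, so the recovery need not carry over to the real comparison. Alternatives were another pseudocount (0.1), no filter, a mean of at least 5 FPKM, medians made equal, quantile normalization, scaling to a sum of 1000000, limma without trend and robust moderation, adjusted p below 0.01, the replicate number as a block and leaving out each library. After the data were seen, scaling without mitochondrial genes, the most abundant transcript in place of the sum, genes with 1 listed transcript, and library sums made equal at their mean with the same genes and pseudocount were added.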

Results

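RNA sequencing was used to compare 6 samples of 92.1, an established human cell line derived from a uveal melanoma, a tumour of the pigment cells of the eye. In the DMSO group, 3 samples received the solvent alone, and in the LBH589 group, 3 samples received 0.1 µM LBH589 for 24 h. LBH589 (panobinostat) is a small molecule that inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) of 30624 transcripts, which were summed to 12010 named genes. Summed FPKM was 409742 ± 12731 per DMSO library and 361610 ± 6082 per LBH589 library (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest p that 3 against 3 samples allow). The files hold no counts, so the absolute depth of the libraries is unknown. Genes at 1 FPKM or more numbered 9949 ± 182 in DMSO and 10450.3 ± 78.6 in LBH589 (exact permutation p = 0.1). Mitochondrially encoded genes held 41.9 ± 5.27% of FPKM in DMSO and 36.2 ± 1.10% in LBH589 (exact permutation p = 0.3). The labels name no separate cultures or batches, so p-values measure only the spread between these samples, which may be technical.

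The samples separated by treatment. The first principal component of log2(FPKM + 1) held 74.5% of the variance, with DMSO scores between -55.71 and -53.19 and LBH589 scores between 52.85 and 56.09. On the second component the DMSO libraries lay apart, with scores of 35.91, -7.35 and -28.95 for replicates 1 to 3. LBH589 scores there lay between -7.01 and 5.21. Pearson correlations across genes lay between 0.944 and 0.961 within DMSO, between 0.963 and 0.967 within LBH589 and between 0.797 and 0.822 across the groups. Genes are not independent replicates, so these correlations describe the libraries only.

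**Figure D1:**
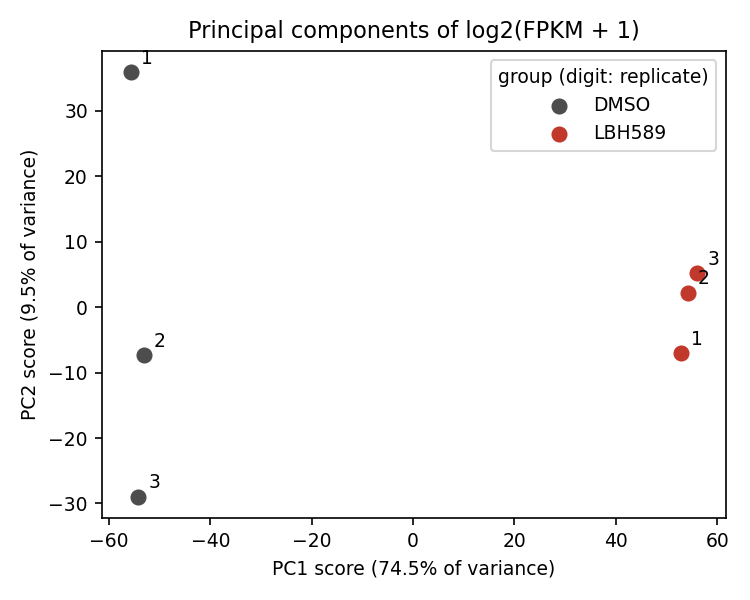
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis, 74.5% and 9.51%. Points are libraries, colours are groups and digits are replicate numbers; the DMSO libraries lie near -54 and the LBH589 libraries near 54 on the first component.

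The comparison of LBH589 with DMSO asked which transcripts of these cells differ after 24 h of histone deacetylase inhibition. The largest rises on the log2(FPKM + 1) scale were those of CGA, CHGA and CTGF. CGA, the alpha chain of the glycoprotein hormones (ENST00000627148.2_1 is its most abundant listed transcript), was listed at 0, 0.418 and 0.317 FPKM in DMSO replicates 1 to 3 and reached 688 ± 50.6 FPKM (SD, n = 3) in LBH589. CHGA, a protein of neuroendocrine secretory granules (ENST00000216492.9_4), rose from 0.204 ± 0.0515 to 106 ± 16.2 FPKM, and CTGF, a secreted matrix-associated protein, rose from 0.855 ± 0.0995 to 135 ± 7.75 FPKM. The largest falls on the log2(FPKM + 1) scale were those of SLC24A5 and SOX10. SLC24A5, an ion exchanger of the melanosome (ENST00000341459.7_1), fell from 106 ± 24.2 to 1.404 ± 0.196 FPKM, and SOX10, a transcription factor of the melanocyte lineage (ENST00000396884.6_1), fell from 69.4 ± 18.3 to 0.688 ± 0.244 FPKM.

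Of 11520 genes tested with limma, 3132 rose and 2485 fell at adjusted p below 0.05, and 1526 of the rises and 1227 of the falls were at least 2-fold on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. All 3 values of a group lay beyond all 3 of the other in 6849 genes, where chance gives 10%. Making the library sums equal, with the same genes and pseudocount, gave 3730 rises and 2009 falls, so that rises made up 65% of the calls in place of 55.8%. It moved the median log2 fold change of all tested genes from 0.08 to 0.22, and values below are relative to the deposited FPKM. Scaling to a sum of 1000000, which also let 12010 genes pass the filter and raised values against the pseudocount, gave 3934 rises and 2052 falls (65.7% rises) and a median of 0.27. Rises of at least 2-fold numbered 1908 with equal sums and 2453 at 1000000. Other settings lowered the share of rises, to 53.8% with equal medians, 51.7% after quantile normalization and 51.4% at a mean of at least 5 FPKM. After quantile normalization and at 5 FPKM, falls of at least 2-fold outnumbered such rises, 1385 against 1341 and 844 against 790. With the most abundant transcript in place of the sum of transcripts, 3780 of 5584 calls remained in the same direction; among the genes named here, the calls of BCL2L11, BID, EPCAM, HDAC3, HDAC4, MCM4, MITF, MT-ATP6, RPL11 and UHRF1 ended.

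The 10 largest rises, taken by a rule fixed before the data were examined, were CGA (log2 fold change 9.12, SE 0.15, adjusted p = 4.47e-06), CHGA (6.47), CTGF (6.20), NTS (6.02), VGF (5.84), DHRS2 (5.72), HIST1H1C (5.70), SCG2 (5.51), HIST2H2BE (5.44) and CLU (5.41). NTS, the precursor of the peptide neurotensin, was listed at 0, 0.527 and 0.136 FPKM in the DMSO replicates and at 76.9 ± 3.31 FPKM in LBH589. VGF, the precursor of several neuropeptides, was at 14.9, 1.08 and 2.702 FPKM in the DMSO replicates and rose to 283 ± 12.4 FPKM; its log2 fold change was 6.68 without DMSO replicate 1 and 5.21 without DMSO replicate 2. DHRS2, a short-chain dehydrogenase, was listed at 0.0665, 0 and 0 FPKM in DMSO and at 46.5, 42.2 and 75.2 FPKM in LBH589. CLU, a secreted chaperone, rose from 1.29 ± 0.827 to 94.3 ± 23.2 FPKM. The 10 largest falls were SLC24A5 (log2 fold change -5.46, SE 0.18, adjusted p = 1.83e-05), SOX10 (-5.36), TRPM1 (-5.17), MLIP (-5.01), HTR2B (-4.96), EMCN (-4.69), TRIM63 (-4.47), ASB11 (-4.45), RASGRP3 (-4.28) and CABLES1 (-4.26). TRPM1, a cation channel of melanocytes, was at 42.1 ± 4.24 FPKM in DMSO and at 0.597, 0 and 0.0623 FPKM in the LBH589 replicates. HTR2B, a serotonin receptor, fell from 32.7 ± 2.82 to 0.0793 ± 0.0594 FPKM, and TRIM63, a ubiquitin ligase, fell from 50.4 ± 2.71 to 1.33 ± 0.186 FPKM.

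**Figure D2:**
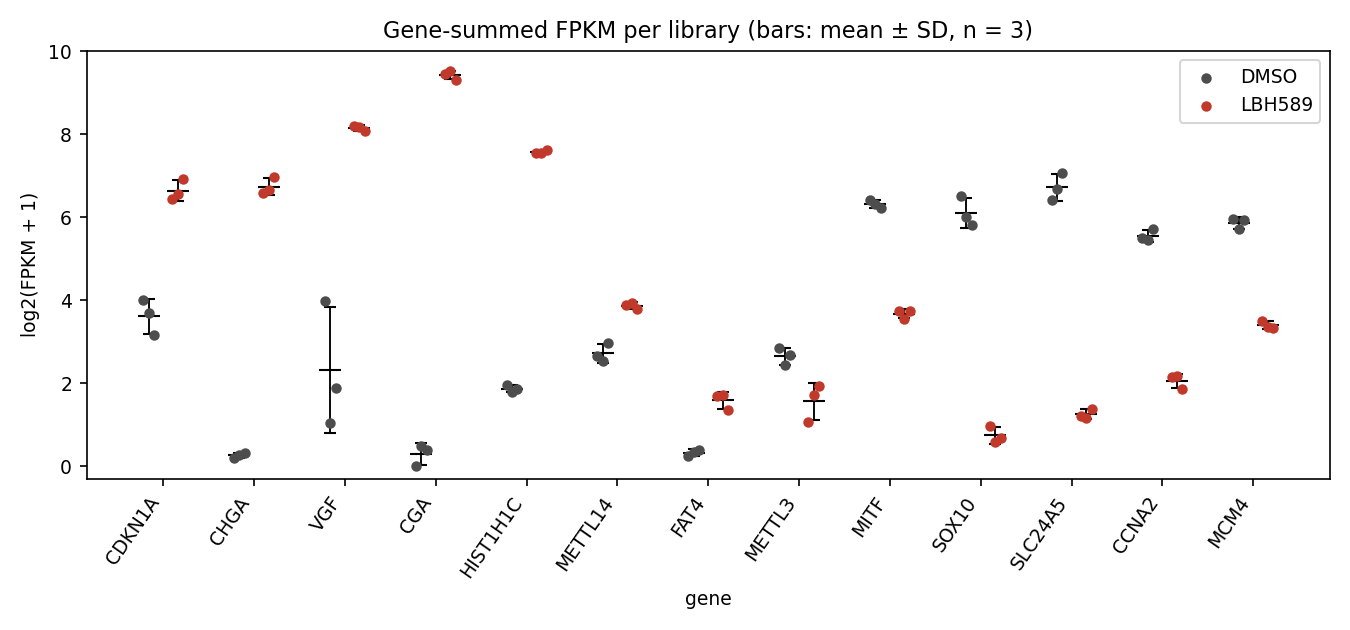
Gene-summed expression on the log2(FPKM + 1) axis for 13 genes named in the text; points are single libraries, and black bars give the mean and SD of each group (n = 3). LBH589 libraries lie above DMSO libraries for CDKN1A, CHGA, VGF, CGA, HIST1H1C, METTL14 and FAT4 and below them for METTL3, MITF, SOX10, SLC24A5, CCNA2 and MCM4.

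Genes long used as markers of histone deacetylase inhibition and histone genes with polyadenylated transcripts rose together. Of 14 tested responsive genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 11.6 ± 3.52 to 99.5 ± 18.3 FPKM (SD, n = 3; log2 fold change 3.01, SE 0.24, adjusted p = 2.16e-04). TXNIP, a binding partner of thioredoxin, rose from 2.34 ± 0.567 to 27.5 ± 0.848 FPKM, and the metallothioneins MT2A and MT1X, which bind metal ions, rose from 8.096 ± 2.34 to 77.96 ± 4.99 FPKM and from 9.13 ± 2.497 to 67.6 ± 3.25 FPKM. Both tested metallothioneins thus rose, though their near-identical copies make the split of fragments uncertain. All 8 tested histone genes rose (8 adjusted over the list alone), among them HIST1H1C, a linker histone, from 2.68 ± 0.219 to 189 ± 5.33 FPKM and HIST1H2BD from 15.4 ± 3.48 to 367 ± 15.9 FPKM. HIST2H2BE went from 0.375 ± 0.118 to 58.6 ± 3.78 FPKM and HIST1H2AC from 1.47 ± 0.486 to 53.7 ± 3.54 FPKM. Histone genes are near-identical copies of each other, so single members are uncertain. Both lists were called by camera with the preset correlation (adjusted p = 0.00132 and 1.29e-05), and neither with an estimated correlation (adjusted p = 0.182 and 0.126). Among genes with 1 listed transcript the first list was not called (adjusted p = 0.0548).

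Neuronal genes, many of them targets of the repressor REST, rose, 17 of 25 from a DMSO mean below 1 FPKM. Of 28 tested, REST itself included, 25 rose and 1, NEFH, fell (25 and 2 adjusted over the list alone). The list has 38 members, of which 31 are listed. A member near 0 FPKM in DMSO could be tested only if higher in LBH589, and a member low in both groups dropped out. That filter therefore shapes part of these counts and of the camera test of the list. SCG2, a granin of secretory granules, rose from 0.152 ± 0.104 to 51.4 ± 1.54 FPKM, CHGB from 0.0797 ± 0.0258 to 15.3 ± 1.504 FPKM and SCG3 from 0.0752 ± 0.0474 to 13.9 ± 0.935 FPKM. NEFH, a neurofilament subunit named after its value was seen, went from 24.3 ± 1.64 to 18.2 ± 0.236 FPKM, a call that ended under scaling to 1000000 (adjusted p = 0.0813). REST itself was at 11.2 ± 0.377 FPKM in DMSO and 8.35 ± 1.73 FPKM in LBH589 (log2 fold change -0.40, adjusted p = 0.0849), which did not pass over all genes. Adjusted over the list alone REST did pass, as the second fall. The list was called upward by camera (adjusted p = 8.98e-10; 0.172 with an estimated correlation).

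Genes of DNA replication and of mitosis fell almost throughout. Of 40 tested G1/S and replication genes, 38 fell and 0 rose (38 falls adjusted over the list alone). TYMS, which makes thymidylate, fell from 50.1 ± 7.18 to 5.43 ± 0.459 FPKM, and MCM4, a subunit of the replicative helicase, from 57.5 ± 5.43 to 9.596 ± 0.7197 FPKM. Of 39 tested G2/M genes, 36 fell and 0 rose (37 falls adjusted over the list alone). TOP2A, a topoisomerase, fell from 82.9 ± 7.603 to 8.55 ± 0.462 FPKM, the cyclin CCNA2 from 45.9 ± 4.69 to 3.195 ± 0.479 FPKM and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, from 35.4 ± 5.703 to 0.956 ± 0.217 FPKM. Of 25 homologous recombination and Fanconi genes, 15 fell, with EXO1 from 64.5 ± 4.91 to 3.67 ± 0.565 FPKM and FANCD2 from 6.17 ± 0.272 to 0.552 ± 0.147 FPKM, and 1, FANCL, rose (17 and 1 adjusted over the list alone; 15 falls and 3 rises with equal sums). FANCL, named after its value was seen, went from 28.5 ± 2.13 to 50.04 ± 4.69 FPKM. Camera called the G1/S, G2/M and recombination lists downward (adjusted p = 1.89e-15, 5.46e-19 and 3.61e-05), and none with an estimated correlation (adjusted p = 0.0755, 0.0747 and 0.0755). Restricting to genes with a mean of at least 5 FPKM ended the call of the recombination list (adjusted p = 0.155). Of 7 CDK inhibitors, 3 rose and 1 fell (4 and 1 adjusted over the list alone; list not called, adjusted p = 0.354). CDKN1C rose from 6.57 ± 0.588 to 55.3 ± 15.4 FPKM, CDKN2B was listed at 0, 2.07 and 1.54 FPKM in DMSO and 14.6 ± 1.08 FPKM in LBH589, and CDKN1B fell from 12.3 ± 2.18 to 6.37 ± 0.784 FPKM.

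Melanocyte identity and pigmentation genes fell. Of 23 tested, 20 fell and 0 rose (20 falls adjusted over the list alone). MITF, the transcription factor that controls pigment genes, fell from 78.8 ± 5.31 to 11.8 ± 0.966 FPKM (log2 fold change -2.64, SE 0.10, adjusted p = 2.43e-05). MLANA, a melanosomal protein, fell from 244 ± 12.9 to 16.7 ± 0.682 FPKM, and TYR, the enzyme of the first step of melanin synthesis, from 116 ± 4.94 to 9.56 ± 1.19 FPKM. PMEL, which forms the melanosome fibrils, was at 274 ± 89.6 and 200.03 ± 24.6 FPKM and did not pass (adjusted p = 0.239; 0.0351 without DMSO replicate 3), nor did MC1R (1.14 ± 0.725 and 0.421 ± 0.262 FPKM) and BCAN (33.2 ± 12.03 and 24.1 ± 8.699 FPKM), though MC1R did after quantile normalization (adjusted p = 0.0189). Camera called the list downward (adjusted p = 7.65e-12; 0.0747 with an estimated correlation). With the most abundant transcript in place of the sum, MITF had a log2 fold change of 0.06 (adjusted p = 0.979); that transcript was listed at 74.4, 1.27 and 5.25 FPKM in DMSO replicates 1 to 3.

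**Figure D3:**
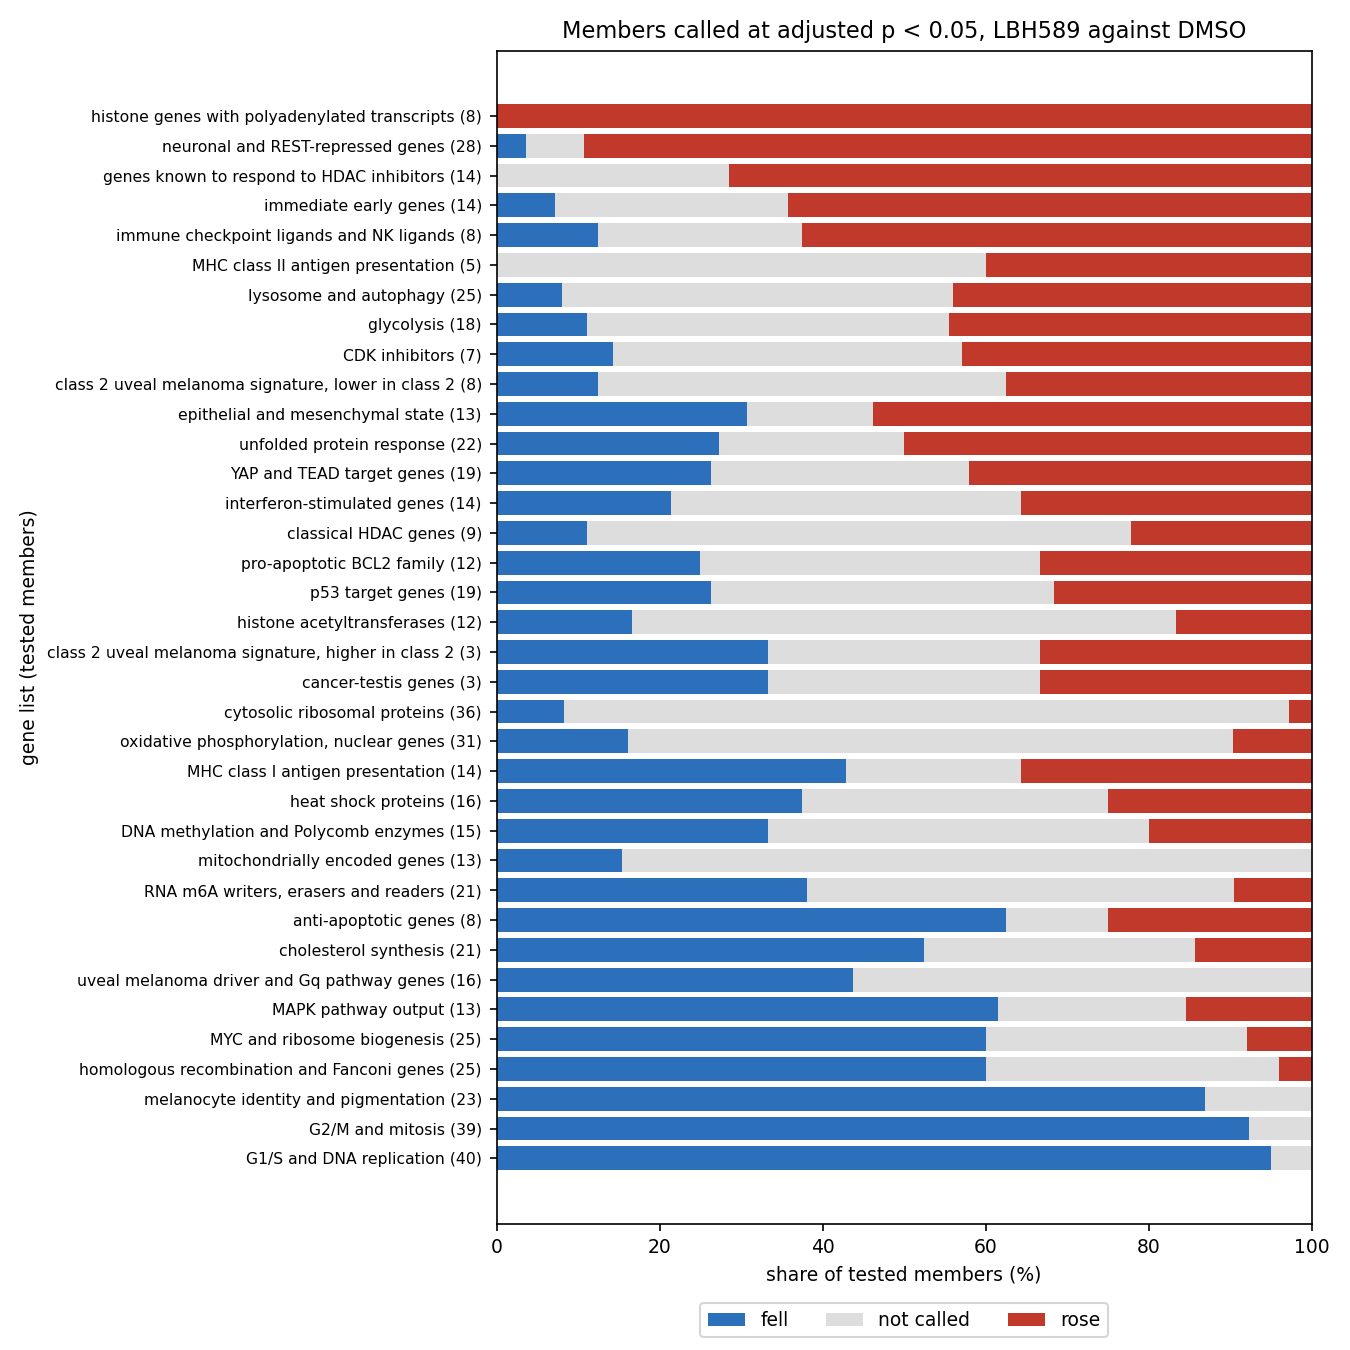
Share of tested members of each gene list that fell (blue), were not called (grey) or rose (red) at limma adjusted p below 0.05, with the number of tested members in brackets, for the 36 lists with at least 3 tested members. Histone genes (8 of 8 rose) stand at one end and G1/S genes (38 of 40 fell) near the other.

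The RNA m6A methylation genes and FAT4 were named beforehand because the study's authors are known to have examined them. METTL14, a subunit of the m6A methyltransferase (ENST00000388822.9_1), rose from 5.65 ± 1.04 to 13.7 ± 0.828 FPKM (SD, n = 3; log2 fold change 1.15, SE 0.14, adjusted p = 0.00111). METTL3, its catalytic partner (ENST00000298717.8_1), fell from 5.35 ± 0.891 to 2.07 ± 0.875 FPKM (log2 fold change -1.08, SE 0.25, adjusted p = 0.0142). FAT4, an atypical cadherin (ENST00000394329.7_1), rose from 0.2596 ± 0.0668 to 2.03 ± 0.414 FPKM (log2 fold change 1.26, SE 0.15, adjusted p = 8.38e-04). Its DMSO mean is below 0.5 FPKM, so FAT4 was listed only through its LBH589 values. Of 6 FAT and dachsous cadherins, 2 are listed, FAT4 and FAT1. FAT1 was at 65.1 ± 17.1 and 54.9 ± 4.16 FPKM and did not pass (adjusted p = 0.436); without DMSO replicate 1 it passed, at a log2 fold change of -0.43. The demethylases ALKBH5 (9.29 ± 3.83 and 17.2 ± 5.101 FPKM, adjusted p = 0.0858) and FTO (2.57 ± 1.74 and 3.82 ± 1.81 FPKM, adjusted p = 0.4504) did not pass, though ALKBH5 did without DMSO replicate 1 (adjusted p = 0.0378) or LBH589 replicate 2 (0.0492). Of 21 writers, erasers and readers, 2 rose and 8 fell (the same counts adjusted over the list alone; list not called, adjusted p = 0.167), against 4 and 7 with equal sums and 1 and 8 with equal medians. Among the falls were the reader IGF2BP1, from 13.96 ± 0.669 to 1.32 ± 0.207 FPKM, and ZC3H13, a writer subunit, from 436 ± 35.6 to 106 ± 2.24 FPKM. The study may have chosen METTL14 and FAT4 on these samples, in which case their changes are no independent evidence.

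Among the targets of the drug, HDAC4 fell from 5.07 ± 0.534 to 2.65 ± 0.179 FPKM (adjusted p = 0.00461), HDAC5 rose from 3.93 ± 1.8003 to 9.74 ± 1.26 FPKM (0.0169) and HDAC3 rose from 8.62 ± 3.75 to 17.1 ± 4.05 FPKM (0.0458). The HDAC5 call ended without LBH589 replicate 2 or 3 (adjusted p = 0.0533 and 0.0594), and that of HDAC3 without DMSO replicate 2 or 3 (0.0975 and 0.1) or LBH589 replicate 1, 2 or 3 (0.0644, 0.0956 and 0.134). HDAC1 (7.44 ± 1.76 and 18.5 ± 13.3 FPKM), HDAC2 (24.8 ± 13.9 and 8.57 ± 4.12 FPKM), HDAC6 (2.99 ± 1.17 and 4.44 ± 0.678 FPKM), HDAC8 (10.9 ± 0.926 and 10.6 ± 0.558 FPKM), HDAC9 (2.54 ± 1.12 and 2.68 ± 0.621 FPKM) and HDAC10 (0.501 ± 0.209 and 0.556 ± 0.531 FPKM) did not pass. Without DMSO replicate 1, HDAC2 passed at a log2 fold change of -1.90 (adjusted p = 0.0101) and HDAC6 at 0.71 (0.0158). HDAC7 was not analysed here, and HDAC11 was listed at 0 FPKM in DMSO and at 0.923, 0.216 and 0.731 FPKM in LBH589, below the level tested. The HDAC list was not called (adjusted p = 0.909; 1 rise and 1 fall adjusted over the list alone). Of 12 acetyltransferases, 2 rose, among them NCOA1 from 5.54 ± 0.572 to 9.96 ± 0.4899 FPKM, and 2 fell, among them KAT2A from 3.31 ± 0.725 to 1.45 ± 0.294 FPKM (1 and 1 adjusted over the list alone; list adjusted p = 0.823). Equal sums made that 3 rises and 1 fall, and quantile normalization or equal medians 1 and 2. Of 15 DNA methylation and Polycomb genes, 3 rose and 5 fell (the same counts adjusted over the list alone; list adjusted p = 0.411), against 4 and 4 with equal sums, where the median log2 fold change turned from -0.06 to 0.11. UHRF1, which recruits the maintenance DNA methyltransferase, fell from 18.4 ± 3.53 to 2.22 ± 0.256 FPKM, and DNMT3A, a DNA methyltransferase, from 5.38 ± 1.75 to 0.125 ± 0.0121 FPKM.

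Genes tied to uveal melanoma moved in part. Of 16 driver and Gq pathway genes, 7 fell and 0 rose (7 falls adjusted over the list alone; list adjusted p = 0.152), against 6 and 3 with equal sums, where the median log2 fold change turned from -0.10 to 0.07. RASGRP3, an activator of RAS, fell from 92.8 ± 11.3 to 3.82 ± 0.505 FPKM and YAP1, a transcriptional coactivator, from 29.8 ± 2.12 to 10.8 ± 0.893 FPKM. BAP1, a deubiquitinase and tumour suppressor, was at 5.34 ± 2.01 and 8.25 ± 1.34 FPKM and did not pass (adjusted p = 0.118), though it did without DMSO replicate 1 (0.0479). Of the genes higher in class 2 tumours, the class with more metastasis, HTR2B fell, ECM1 rose to 3.55 ± 0.897 FPKM from 0.0983, 0.351 and 0 FPKM in the DMSO replicates, and RAB31 (5.04 ± 0.302 and 3.62 ± 1.195 FPKM) did not pass (1 rise and 1 fall adjusted over the list alone; list adjusted p = 0.506). Of 8 genes lower in class 2 tumours, 3 rose and 1 fell, with ROBO1 from 8.17 ± 1.72 to 42.1 ± 2.86 FPKM and LMCD1 from 5.03 ± 0.894 to 16.1 ± 1.96 FPKM (3 rises and 2 falls adjusted over the list alone, 3 and 0 with equal sums; list adjusted p = 0.532). Of 13 genes of MAPK pathway output, 8 fell and 2 rose (the same counts adjusted over the list alone). CCND1, a cyclin of G1, fell from 99.7 ± 1.24999 to 12.5 ± 0.754 FPKM and SPRY4, a feedback inhibitor, from 26.9 ± 2.48 to 4.66 ± 0.465 FPKM. Camera called the MAPK list downward (adjusted p = 0.0129; 0.172 with an estimated correlation, and 0.0656 among genes with 1 listed transcript). Of 19 YAP and TEAD targets, 8 rose and 5 fell (9 and 5 adjusted over the list alone; list adjusted p = 0.251). CYR61, a secreted matrix-associated protein, rose from 4.899 ± 0.4799 to 172 ± 12.4 FPKM and IGFBP3 from 1.198 ± 0.121 to 13.4 ± 0.871 FPKM. ANKRD1 was listed at 0 FPKM in all 3 DMSO libraries and at 5.88, 5.001 and 4.85 FPKM in LBH589.

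Genes of ribosome biogenesis and cholesterol synthesis mostly fell, and immediate early genes mostly rose. In the MYC and ribosome biogenesis list, 15 of 25 fell and 2 rose (16 and 2 adjusted over the list alone). NOP16 fell from 42.1 ± 4.45 to 12.2 ± 0.412 FPKM and DKC1, a pseudouridine synthase, from 46.2 ± 4.504 to 14.6 ± 0.116 FPKM, while ODC1, the first enzyme of polyamine synthesis, rose from 35.3 ± 11.2 to 466 ± 27.3 FPKM. MYC was at 184, 3.47 and 143 FPKM in DMSO and 1.86, 2.84 and 14.8 FPKM in LBH589 and did not pass (adjusted p = 0.141), though it did without DMSO replicate 2 (0.00681). In cholesterol synthesis, 11 of 21 fell and 3 rose (the same counts adjusted over the list alone). FDFT1, a squalene synthase, fell from 159.98 ± 5.704 to 46.2 ± 4.201 FPKM, while IDI1 rose from 113 ± 5.0002 to 287 ± 28.5 FPKM. Of 14 immediate early genes, 9 rose and 1, NR4A3, fell (the same counts adjusted over the list alone). JUN rose from 2.99 ± 0.413 to 51.98 ± 3.38 FPKM and FOS from 2.08 ± 0.393 to 19.97 ± 3.103 FPKM, while NR4A3, named after its value was seen, went from 77.99 ± 9.59 to 44.4 ± 10.7 FPKM. Camera called the 3 lists (adjusted p = 3.61e-04, 0.0195 and 0.0353), and none with an estimated correlation (adjusted p = 0.272, 0.172 and 0.272). The call of the immediate early list ended without DMSO replicate 1 (adjusted p = 0.0738) or 2 (0.0571), without a filter (0.0855), under scaling to 1000000 (0.157; 0.0854 without mitochondrial genes) and among genes with 1 listed transcript (0.0757). The call of the MYC list also ended among genes with 1 listed transcript (adjusted p = 0.0535), and that of the cholesterol list with the most abundant transcript in place of the sum (0.144).

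Apoptosis and p53 genes went both ways. Of 12 pro-apoptotic BCL2 family genes, 4 rose and 3 fell, with BCL2L11 from 1.33 ± 0.143 to 12.8 ± 1.09 FPKM and BID from 5.804 ± 0.1598 to 0.172 ± 0.0913 FPKM (list adjusted p = 0.718; 4 and 4 after quantile normalization). Of 8 anti-apoptotic genes, 5 fell, with BCL2 from 22.4 ± 2.63 to 6.29 ± 0.4595 FPKM, and 2 rose, with MCL1 from 28.7 ± 2.28 to 66.5 ± 10.96 FPKM (list adjusted p = 0.197). Of 19 p53 targets, 6 rose and 5 fell, with BTG2, an antiproliferative factor, from 2.87 ± 0.547 to 8.47 ± 0.888 FPKM and RRM2B, a ribonucleotide reductase subunit, from 9.15 ± 0.8998 to 16.4 ± 0.743 FPKM (list adjusted p = 0.998; 6 and 7 after quantile normalization). Counts adjusted over the list alone were the same for these 3 lists.

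Immune genes also went both ways. Of 14 interferon-stimulated genes, 5 rose and 3 fell, among the falls IFIT3 from 4.12 ± 0.343 to 0.176 ± 0.0715 FPKM (list adjusted p = 0.909). After quantile normalization 4 rose and 6 fell, and the median log2 fold change of that list turned from 0.11 to -0.02. Of 14 MHC class I genes, 5 rose and 6 fell, with HLA-B from 19.1 ± 5.42 to 57.4 ± 8.24 FPKM and TAPBP, a chaperone of peptide loading, from 21.5 ± 1.42 to 5.53 ± 0.295 FPKM. The median log2 fold change of that list was 0.39, while camera's direction was down (adjusted p = 0.849). Of 5 MHC class II genes, 2 rose, with HLA-DMB from 5.61 ± 2.44 to 17.9 ± 2.53 FPKM and HLA-DRB1 listed at 0, 0.116 and 0 FPKM in DMSO and 1.197, 1.09 and 0.742 FPKM in LBH589 (list adjusted p = 0.470). HLA genes share near-identical sequence, so the values of single HLA genes are uncertain. Of 8 checkpoint and NK cell ligands, 5 rose and 1, PVR, fell (list adjusted p = 0.354). ULBP2, a stress ligand, rose from 1.11 ± 0.251 to 4.66 ± 0.739 FPKM and MICA from 17.7 ± 3.91 to 33.2 ± 1.18 FPKM, while PVR, an adhesion receptor, fell from 19.2 ± 1.13 to 5.64 ± 0.792 FPKM. Counts adjusted over the list alone were the same for these 4 lists.

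Stress response genes changed in both directions. Of 22 genes of the unfolded protein response, 11 rose and 6 fell (11 and 7 adjusted over the list alone; list adjusted p = 0.478), with DDIT4 from 4.23 ± 1.28 to 26.8 ± 1.80001 FPKM and PPP1R15A from 16.4 ± 2.23 to 50.3 ± 2.61 FPKM. Of 16 heat shock genes, 4 rose and 6 fell (the same adjusted over the list alone; list adjusted p = 0.470), with HSPA8, a constitutive chaperone, from 688 ± 53.7 to 160.2 ± 24.03 FPKM and DNAJB1 from 30.1 ± 10.9 to 133 ± 1.27 FPKM.

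Of 25 lysosome and autophagy genes, 11 rose and 2 fell (the same adjusted over the list alone; list adjusted p = 0.197), with NEU1, a lysosomal sialidase, from 19.97 ± 7.03 to 151 ± 23.03 FPKM and CTSL, a cathepsin, from 94.7 ± 5.57 to 35.7 ± 1.09 FPKM. Of 18 glycolysis genes, 8 rose and 2 fell (the same adjusted over the list alone; 9 and 1 with equal sums; list adjusted p = 0.283), with TPI1 from 110.01 ± 42.7 to 961 ± 53.8 FPKM and ALDOA from 87.6 ± 19.4 to 391 ± 1.37 FPKM. Of 31 nuclear genes of oxidative phosphorylation, 3 rose and 5 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.470), with NDUFB3 from 40.4 ± 3.22 to 67.02 ± 6.93 FPKM and NDUFA1 from 104 ± 15.8 to 53.003 ± 6.13 FPKM. Equal sums or scaling to 1000000 made that 4 rises and 3 falls, and turned the list's median log2 fold change from -0.06 to 0.12. Of 36 ribosomal protein genes, 1 rose, RPS18 from 477 ± 127 to 859.9 ± 54.6 FPKM, and 3 fell, among them RPL11 from 1527 ± 63.5 to 1227 ± 44.4 FPKM. Adjusted over the list alone none of these was called, and camera did not call the list (adjusted p = 0.609); its median log2 fold change, -0.05, had the other sign with equal sums (0.13) or scaling to 1000000 (0.13), both with 2 rises and 0 falls, and after quantile normalization (0.06), with 3 rises and 2 falls. Its mean was 0.04, and scaling without mitochondrial genes gave 3 rises and 3 falls. The fall of RPL11 lost its call without DMSO replicate 2 (adjusted p = 0.11) or LBH589 replicate 1, 2 or 3 (0.103, 0.0915 and 0.108), under scaling to 1000000 (0.292) and after quantile normalization (0.828). Of 13 mitochondrially encoded genes, 0 rose and 2 fell, MT-ATP8 and MT-ATP6, whose sequences overlap, and none adjusted over the list alone (list adjusted p = 0.251; 0.0474, downward, without DMSO replicate 1). The median log2 fold change of that list turned from -0.15 to 0.03 with equal sums, with 1 fall, and to 0.07 after quantile normalization, with 1 rise and 1 fall. MT-ATP6 was listed at 5439.6, 29373 and 27712 FPKM in DMSO and 4691, 4070.2 and 3990.3 FPKM in LBH589, with a log2 fold change of -1.95 that became -2.75 without DMSO replicate 1. Its call ended without any other single library (highest adjusted p 0.134) and under scaling to 1000000 (0.0609), with a pseudocount of 0.1 (0.0522), without a filter and among genes with 1 listed transcript. MT-ATP8 went from 33886 ± 4087 to 22893 ± 1281 FPKM, a call that ended without DMSO replicate 2 (adjusted p = 0.0532) or LBH589 replicate 1 or 3 (0.0518 and 0.0523) and after quantile normalization.

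Of 13 genes of epithelial and mesenchymal state, 7 rose and 4 fell (the same adjusted over the list alone; list adjusted p = 0.470). CDH2, a cadherin of mesenchymal and neural cells, rose from 0.215 ± 0.0716 to 15.99 ± 1.61 FPKM, SNAI2, a transcription factor of mesenchymal state, fell from 140.1 ± 18.7 to 33.9 ± 1.34 FPKM, and MMP14, a membrane-bound protease, fell from 47.1 ± 10.4 to 3.28 ± 0.475 FPKM. Of 3 tested cancer-testis genes, SSX1 fell from 6.73 ± 1.03 to 0.402 ± 0.0379 FPKM and MAGEA6, which has near-identical copies, was listed at 0.164, 0.135 and 0 FPKM in DMSO and 2.03, 1.72 and 1.37 FPKM in LBH589 (1 rise and 1 fall, the same adjusted over the list alone; list adjusted p = 0.986).

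Markers of other cell types were few in the files. The endothelial marker EMCN fell from 41.8 ± 3.82 to 0.683 ± 0.402 FPKM, and the leukocyte marker CD68 was at 13.9 ± 2.63 and 10.1 ± 2.99 FPKM without passing (adjusted p = 0.180). The fibroblast markers LUM and COL1A1 rose from 0.721 ± 0.152 to 1.42 ± 0.0158 FPKM and from 1.13 ± 0.723 to 3.32 ± 0.705 FPKM, the latter not called without DMSO replicate 2 (adjusted p = 0.0587) or LBH589 replicate 1 (0.0586) and LUM not after quantile normalization (0.186). The epithelial marker EPCAM rose from 0.313 ± 0.132 to 0.835 ± 0.245 FPKM, a call that ended without DMSO replicate 2 or 3 (adjusted p = 0.0926 and 0.0995) or LBH589 replicate 1 or 2 (0.0566 and 0.0594) and after quantile normalization (0.376). KRT18, at 6.43 ± 1.33 and 8.91 ± 1.23 FPKM, did not pass (adjusted p = 0.0934), though it did without DMSO replicate 1 (0.0434) and under scaling to 1000000 (0.0419). The retinal pigment epithelium marker RLBP1 fell from 1.53 ± 0.348 FPKM to 0.254, 0 and 0.198 FPKM in the LBH589 replicates. BEST1, another marker of that tissue, was at 5.93 ± 0.479 and 5.65 ± 2.11 FPKM. Counts adjusted over the list alone were the same for these 5 lists, and no other member reached the level tested.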

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

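The tests on other splits of the samples in this part were written down after their results were seen. Transcripts whose identifiers matched no gene name were left out of the comparison, and signal above the control level appeared among them. Of 99 such transcripts tested in the same limma fit as the named ones, 16 rose and 5 fell with LBH589 at adjusted p below 0.05, and 30 had an unadjusted p below 0.05. Their genes are not named here.

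The real grouping of the 6 samples called 5617 genes, and the highest count among the other 9 splits was 0. Since 3 against 3 samples make 10 splits, of which 1 gave as many calls, the splits are too few to test whether grouping by chance gives such a count. For the gene lists, 2 of the 10 splits gave as many calls as the real 11, and the other 9 splits gave between 5 and 11. Each other split sets 2 libraries of a treatment and 1 of the other against the reverse, so part of the treatment difference remains in it, and the list test compares the members with other genes.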

How the results depend on the processing

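The settings with the most abundant transcript, 1 listed transcript, scaling without mitochondrial genes and equal library sums were chosen after seeing the data; the planned count normalizations and count tests were not run, since the files hold FPKM. No call of the 5617 reversed direction in any setting except with the most abundant transcript in place of the sum, where 137 of 5584 did and 2 were called in the other direction. At a mean of at least 5 FPKM, where 6866 genes were tested, 1844 rose and 1746 fell, 790 and 844 of them at least 2-fold. Quantile normalization gave 2889 rises and 2701 falls, 1341 and 1385 of them at least 2-fold. Under scaling to 1000000, rises of at least 2-fold numbered 2453 and such falls 1172. Genes with 1 listed transcript, of which 3994 were tested, gave 1263 rises and 832 falls, 569 and 339 of them at least 2-fold, and 6 called lists. Of the lists, 0 were called with an estimated correlation and 26 by fry, which tests whether a list's genes move one way and not against other genes. Leaving out single libraries gave between 2509 and 3277 rises and between 2056 and 2406 falls. Without DMSO replicate 1, 6 named genes gained a call and 0 lost it. Leaving out any other library ended between 3 and 6 named calls and gained at most 1. Deviations of same-numbered samples hardly correlated (-0.104, 0.021 and -0.035), which cannot exclude that these samples were handled together. With the replicate block 2617 rose and 2172 fell, and 10 lists were called. The immediate early list lost its call there (camera adjusted p = 0.051). Over its 18 alternatives its adjusted p ranged from 0.00998 to 0.157, and 8 ended its call, among them equal sums (0.0761). The block also ended the calls of EPCAM, HDAC3, LUM, MT-ATP6, NEFH, NR4A3 and RPL11 among 121 named genes called. The most abundant transcript ended 10 of these 121 calls, scaling to 1000000 or equal sums ended 3 each and quantile normalization 4, while equal medians, limma without trend and robust moderation, and scaling without mitochondrial genes ended 0 of those tested. The sign reversed in at least 1 setting for 11 named genes, with no adjusted p below 0.291 there. Of these genes, MITF alone was called in the reported comparison. With the most abundant transcript the log2 fold change was 0.0595 for MITF, -0.46 for BAP1, 0.28 for BCAN, 0.0343 for FAT1, -0.25 for FTO, -0.052 for HDAC6, 0.14 for HDAC8 and 0.0173 for PMEL. Scaling to 1000000 gave 0.0351 for BEST1 and 0.15 for HDAC8 (0.0146 without mitochondrial genes), equal sums 0.038 for BEST1, 0.0522 for HDAC10 and 0.14 for HDAC8, and quantile normalization -0.0271 for HDAC9. Leaving out single libraries gave ranges of -0.29 to 0.18 for BEST1, -0.0835 to 0.29 for HDAC10, -0.0922 to 0.0147 for HDAC8 and -0.14 to 0.32 for HDAC9. The cause was not tested; for MITF, the transcript used was listed at 74.4, 1.27 and 5.25 FPKM in DMSO replicates 1 to 3 and the gene sum at 84.1, 78.8 and 73.4 FPKM. Relative depth was estimated for 4 libraries, taking 1 step as equal fragments in each, and absolute depth for none. No limit of detection can therefore be given.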

Other observations

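Families grouped by gene symbol were chosen after the values were seen. Members near 0 FPKM in DMSO could be tested only if higher in LBH589. This filter favours rises, among others in the potassium channels and histones. Camera called 3 of the 31 families upward and 5 downward, and 0 with an estimated correlation. Several families share members with the lists above, so their calls are in part no separate evidence. KIF2C and CENPF are in the G2/M list, KIF5C and SNAP25 in the neuronal list and HIST1H1C in the histone list. Of 27 tested histone genes of all clusters, 24 rose and 0 fell, with HIST1H3H from 2.07 ± 0.431 to 56.8 ± 2.76 FPKM and HIST2H2AA3 from 0.378 ± 0.254 to 46.6 ± 7.27 FPKM (SD, n = 3). Of 21 centromere proteins, which build the kinetochore, 14 fell and 1 rose, with CENPF from 69.5 ± 14.8 to 5.502 ± 0.912 FPKM, CENPU from 39.4 ± 4.94 to 6.61 ± 0.651 FPKM and CENPW from 22.8 ± 4.08 to 2.63 ± 0.197 FPKM. Camera called both families (adjusted p = 8.77e-10 and 8.67e-05), but neither with an estimated correlation (adjusted p = 0.118 for each), and both kept their direction under all 5 other scalings.

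Kinesins, motors that move along microtubules, split. Of 31, 17 fell, among them KIF2C of mitotic spindles, from 10.7 ± 1.19 to 0.562 ± 0.0542 FPKM, and 9 rose, among them KIF5C of neurons, from 0.0546 ± 0.0338 to 11.8 ± 0.336 FPKM. Of 29 synaptotagmins and SNARE genes, which serve vesicle fusion, 13 rose and 1 fell, with SNAP25 from 2.21 ± 0.444 to 14.1 ± 1.75 FPKM. Of 17 potassium channels, 12 rose and 3 fell, with KCND2 from 0.0242 ± 0.0181 to 3.96 ± 0.666 FPKM and KCNJ2 from 0.173 ± 0.0314 to 3.19 ± 0.3997 FPKM. Camera called these families (adjusted p = 0.0328, 0.0477 and 0.0477), not with an estimated correlation (adjusted p = 0.315 for each), and quantile normalization ended each call (0.0824, 0.0824 and 0.1) without turning its direction. The potassium channel call also ended under scaling to 1000000 (0.107) and with equal sums (0.108), and the synaptotagmin and SNARE call with equal sums (0.067). The other called families were mitochondrial ribosomal proteins (19 of 78 fell and 6 rose, adjusted p = 0.0328), splicing factors named SRSF, SNRP or SF3 (14 of 33 fell and 1 rose, 0.0328) and DEAD and DEAH box helicases (16 of 48 fell and 3 rose, 0.0482). Calls of all 3 ended after quantile normalization (0.0893, 0.122 and 0.1) and with equal sums (0.067, 0.067 and 0.085), where 14, 12 and 14 fell and 11, 2 and 8 rose. They also ended under scaling to 1000000 (0.0531, 0.0531 and 0.0857), and that of the helicases ended with equal medians (0.0528) and in scaling without mitochondrial genes (0.0719). Their estimated-correlation p-values were 0.559, 0.365 and 0.513 after adjustment.

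The tests of REST and of MT-ATP6 below were chosen after their values were seen, and the others before. Neuronal genes rose with LBH589, with a median log2 fold change of 2.15 over the 28 tested list members. Across genes, fold change hardly followed GC content (r = -0.051) or log transcript length (r = 0.027). A loess correction for both moved no gene by more than 0.51, and 2440 genes by more than 0.1 from the median correction. It left the list's median at 2.05 (SE 0.41 over the members, taken as independent). This argues against such a trend as the whole cause. The log2 fold change of REST, -0.40 (SE 0.16), argues against a REST transcript level lowered to 50% or less. It does not bear on REST protein or its activity, which were not measured here. Admixed neuroendocrine or neuronal cells cannot be told apart from a change in the melanoma cells: of 15 lineage genes, none of them in the list, 5 are listed and 2 reach 1 FPKM in LBH589, ISL1 (1.76 ± 0.136 and 3.601 ± 0.0947 FPKM) and PCSK2 (1.57 ± 0.614 and 4.58 ± 1.14 FPKM), both also above 1 FPKM in DMSO, and genes outside the files decide nothing. An effect of the treatment on the melanoma cells stays open, untested.

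Replicates of the same group lay far apart in several genes with more than 1 listed transcript. In 1460 genes whose second transcript had a mean of at least 5 FPKM, the median correlation of the within-group deviations of the 2 most abundant transcripts was -0.44, where randomly paired transcripts of different genes gave 0.01, and the median within-group SD on the log2 scale was 0.45 for the most abundant transcript and 0.22 for the gene sum. Fragments assigned to different transcripts of the same gene in different libraries may therefore account for part of the spread. The lower estimated depth of DMSO replicate 3, 0.82 times that of replicate 1, stays open. That library listed 4468 transcripts at 0 against 3374 and 3532 in replicates 1 and 2. Its count of genes at most 10% of both other DMSO values, 1, decides nothing, since such a depth cannot give drops of that size. No biological explanation was tested, and MYC, which differs in its sum, is not explained by a split between listed transcripts.

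The mitochondrial share of FPKM was 35.9% in DMSO replicate 1, 45.8% in replicate 2 and 44.0% in replicate 3, against 35.2 to 37.4% in the LBH589 libraries. Without MT-ATP6 the gap between replicate 1 and the mean of the other DMSO replicates went from 8.99 to 5.82 percentage points, which argues against MT-ATP6 as the whole cause. What raised the share is open, and no biological explanation was tested.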
